A study of Mus musculus with 4 samples.

How the data were processed

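Genomic DNA from intestine of C57BL/6 mice aged 3 and 32 months was hybridised to 2 custom Agilent arrays, and 4 sample records describe the 2 dyes of each array. Cy3 marked the 3-month and Cy5 the 32-month DNA on both arrays, per the labels. The 2 scanner files deposited for an array were identical byte for byte, since each holds both channels, and each channel was used once. The labels give 1 sample per age and array and no dye swap. Per the labels' protocols, DNA was extracted with phenol and chloroform and labelled by Agilent's procedure. The header of the first array's file holds the abbreviation RMCA, which no source used here explains. The step that selects DNA by its methylation, the sex of the animals, the number of animals per sample and the genome build are not given in the sources used here.

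Images were quantified with Agilent Feature Extraction 9.1.3.1, per the submitters' processing notes. The intensity values used were the processed signals, which per the file headers had been background-subtracted, detrended over the array and scaled between dyes by a linear factor without lowess. The mean and local background intensity values of each spot were deposited in the same files. The deposited log10 ratio of red over green signal and the deposited p-value of that ratio, from the scanner's error model for 1 spot, served in alternatives only. The authors' value table for the same arrays equalled the processed signals in 100% of spots on both arrays, so the alternative based on it repeats the main values. No columns remained unmatched to samples.

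For each probe the log2 ratio of processed red over processed green signal was computed and centred on the median of its array. Before centring that median was 0.0044 on the first array and -0.14 on the second. Control spots and probes with a non-uniformity or population outlier flag were left out. A probe was usable when it was well above background in at least 1 channel, which held for 74.2% of positioned probes on the first array and 76.5% on the second. Of 83122 probes, 272 without a position were left out. Signal over background limits the precision. Median mean signals of probes were 113 and 203 in the green and red channels of the first array, against 80 and 107 for the 507 negative controls, and 71.8 and 135 on the second, against 61.7 and 107.

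Neighbouring probes at most 1000 bp apart with the same gene name formed a region, which gave 19141 regions, of which 15353 had at least 2 usable probes. A region's value is the median over its usable probes. It was called higher when that median was at least 1 and every usable probe was above 0, and lower in the mirrored case. No p-value was computed for a difference between the ages, since there is 1 sample per age. The p-values given compare the brightness of germline and housekeeping genes within a sample. Where a dimmer channel was not well above background, a ratio is a bound.

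Positions are those in the files. Of 14572 regions whose gene lies on the same chromosome in the RefSeq table of assembly GRCm38.p6, 7.30% lay within 5000 bp of it, so that table was used for names only. Of 16709 gene names in the files, 12755 were current symbols, 3019 were updated through synonyms and 935 kept the file's name. Among the latter, 20 had been turned into calendar dates by software and were left unnamed.

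Gene lists were fixed before the data were examined, as were the calling rule, the naming rule and most alternative settings. The value of a gene is the mean over its regions. The median of a list was given its percentile among 10000 random lists of the same size matched in 10 bins of brightness (2000 lists under alternatives), and a bootstrap interval over genes from 2000 draws. Genes named in the text are the 12 largest called differences per direction with at least 3 usable probes, up to 4 called members of each of 18 lists, and 8 genes fixed by name. Autosomal regions called lower beyond these, second regions of named genes, genes that escape X inactivation and the brightness of imprinted regions were chosen after values were seen.

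The calling rule was tested on simulated data made from shuffled log ratios of the same 15353 regions, with 100 regions shifted in each direction. At a planted 2-fold shift 53 of 100 were recovered as higher and 47 of 100 as lower. That shift equals the calling threshold, so many such regions fall short of it by construction. At 4-fold these were 100 and 90, and at 8-fold 99 and 95. No planted region was called in the wrong direction. Among the regions without a planted shift, 141 or 142 were called higher and 31 lower at each size of shift. Each planted shift was the same for all probes of a region. Of 20 simulated lists of 50 genes among 14492, 20 ranked above the central range of matched lists at a planted shift of 0.2, 13 at 0.1 and 0 without a shift.

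Alternatives covered uncentred ratios, loess on brightness, normexp background correction with an offset of 50, other probe filters, removal of row and column block medians, other region minimums, means in place of medians, other thresholds and the scanner's p-value. Computations used Python 3.11.15 with numpy, pandas, scipy and statsmodels, and R 4.3.3 with limma 3.58.1 for normexp.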

Results

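The data addressed whether DNA methylation in mouse intestine differs between young and old animals. Genomic DNA from the intestine of C57BL/6 mice, an inbred laboratory strain, was compared between 3 and 32 months of age on 2 custom Agilent oligonucleotide arrays that tile gene promoters and neighbouring sequence. The first array covered chromosomes 1 to 8 and the second covered chromosomes 9 to 19, X and Y, apart from 84 measured regions of chromosomes 9 and 17 that sat on the first. On both arrays the 3-month DNA carried the green dye Cy3 and the 32-month DNA the red dye Cy5. There was 1 sample per age on each array and no array with the dyes exchanged, so each difference below is between single samples, with no replicate check and no test across animals. The number of arrays limits the precision, and each SD given below is a spread over the probes of a region.

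Signal on the arrays was well above background for most probes. On the first array 71.2% of 41545 probes passed in the 3-month channel and 72.5% in the 32-month channel. On the second array the shares were 71.4% and 70.2% of 41577 probes, and no probe was saturated. Neighbouring probes of a gene were joined into regions, of which 15353 had at least 2 usable probes. All ratios are log2 of 32-month over 3-month signal, so that a positive value is a higher signal at 32 months. How the methylated or unmethylated fraction was selected before labelling is not described in the sources used here, beyond an unexplained abbreviation, RMCA, in the header of the first array's file, so values are reported as signal.

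Among called regions with at least 3 usable probes, the highest relative signal at 32 months belonged to Tlx3, a homeobox factor of neuron specification, with a log2 ratio of 5.78 ± 2.01 (SD over 3 probes), a 55.0-fold difference. It lay on chromosome 11 and began at position 33103747, and the array design annotates it as promoter. The serotonin receptor gene Htr1b followed with 5.56 ± 1.03 over 4 probes on chromosome 9 from position 81429040, and the homeobox gene Six6 with 5.23 ± 2.29 over 3 probes on chromosome 12 from position 73858531. Vstm2b had 4.88 ± 1.29 over 6 probes, Trhde, which encodes a peptidase that degrades thyrotropin-releasing hormone, 4.75 ± 1.5 over 4 probes, and the cell adhesion gene Sdk2 4.60 ± 1.48 over 4 probes. The homeobox genes Irx2 and Tlx1 had 4.49 ± 2.17 over 4 probes and 4.40 ± 0.18 over 3 probes. The metalloprotease gene Adamts19 had 4.46 ± 1.01 over 6 probes, and the neuropeptide precursor gene Cartpt 4.29 ± 1.96 over 3 probes. The potassium channel gene Kcnj3 had 4.30 ± 0.80 over 6 probes. The hypothalamic factor gene Sim1 had 4.32 ± 2.31 over 4 probes, of which 3 were well above background at 3 months. When dim probes were kept, Tlx1 and Cartpt lost their calls at medians of 4.10 and 2.11, since a probe then lay on the other side of 0, and Sim1 did so after normexp correction at 4.11. No genome build is stated for these positions.

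Across both arrays 309 regions were called higher at 32 months and 97 were called lower, at a log2 ratio of at least 1 or at most -1 with every usable probe on the same side of 0. The remaining 14947 regions met neither rule. The median fold of the called regions was 2.85 among those higher and 2.65 among those lower, and the calls covered 332 and 110 genes. In 329 of the 406 called regions every probe was well above background in the dimmer sample too, and in 5 none was, so that those 5 ratios are only bounds. Higher calls made up 76.1% of all calls. That share was 64.4% with the scanner's log ratios left uncentred and 95.5% after normexp background correction, when only 20 regions were called lower. With log ratios shuffled among probes of like brightness, the same rule called between 103 and 156 regions higher and between 24 and 54 lower in 100 shuffles. The observed counts thus exceeded the highest count of any shuffle in both directions, while shuffled values alone gave many calls. Median counts in the shuffles were 130.5 higher and 38 lower. Higher calls thus predominated in shuffled values too, and their share of all calls is not by itself a result about regions. Shuffling also parted the neighbouring probes of a region, and the rule demands that these agree. The excess therefore shows agreement among probes of a region in these samples and does not measure variation between animals.

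**Figure D1:**
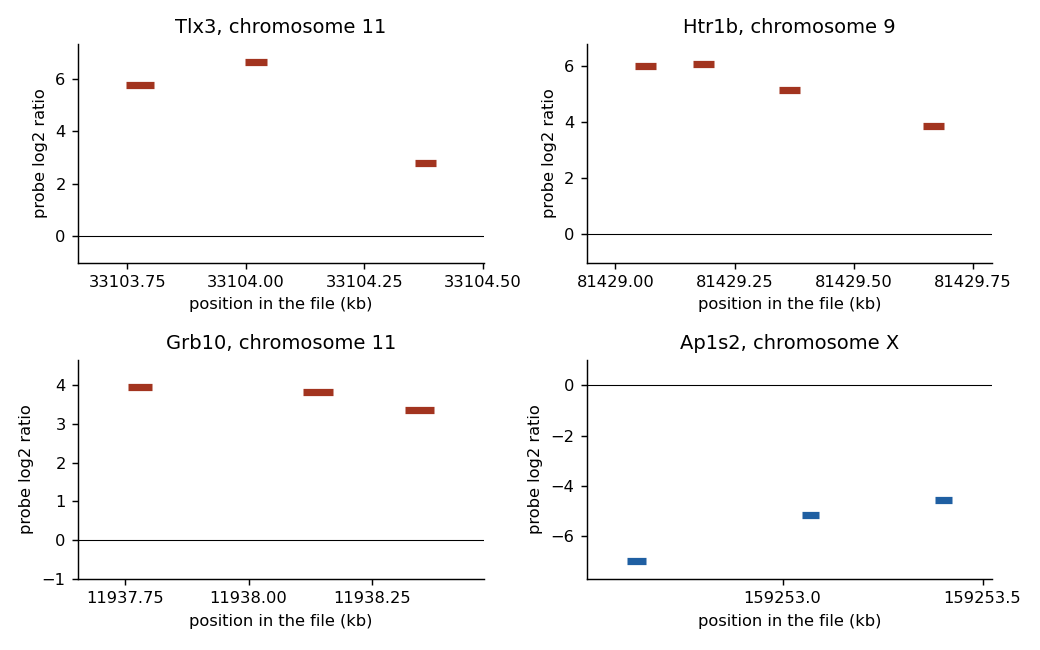
Probe log2 signal ratios (32 over 3 months, vertical axis) against position in kb as given in the files (horizontal axis) at 4 named regions. Each bar is 1 usable probe drawn over its own length. All probes lie above 0 at Tlx3, Htr1b and Grb10 and below 0 at the X-linked Ap1s2.

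Developmental transcription factor genes stood apart from the other gene lists fixed beforehand. Of 187 measured genes of this list, 32 (17.1%) were called higher and 1 was called lower, while 154 met neither rule. The list comprises homeobox, T-box, forkhead, GATA and related factors, many of which pattern the embryo. It shares 2 genes with the immune cell list, of which 1, Tbx21, was called higher. Over all 14492 measured genes 2.29% were called higher. These shares were not matched on brightness, and higher calls were more frequent in brighter regions, as given further below. Whether the share of called genes exceeds that of equally bright genes was not tested, for this list or those below. The median log2 ratio of the list was 0.19, with a 95% bootstrap interval over genes from 0.13 to 0.31, and it lay at percentile 100 of 10000 random gene lists of the same size matched on brightness. Its mean of 0.61 was above its median, and the called members with high ratios were led by Tlx3, Six6, Irx2 and Tlx1. The list stayed at percentile 100 under all 9 alternative settings run, with medians between 0.12 and 0.31 and between 28 and 34 members called higher. The same 32-month sample also differed from the 3-month sample in signal of the X chromosome and of a Y-linked gene, as given further below, and the labels do not state the sex of the animals.

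The 4 Hox clusters, whose genes set position along the body axis, had 3 of 35 measured genes called higher and 1 called lower. Hoxa11 had a log2 ratio of 3.84 ± 2.16 over 5 probes, Hoxd10 1.5 ± 2.14 over 6 probes and Hoxc5 1.12 ± 0.83 over 5 probes, while Hoxa6 had -1.04 ± 1.29 over 2 probes. The list median of 0.11 lay at percentile 92.0 of matched lists, and between 62.8 and 98.4 under the alternatives. Genes of Wnt, Fgf and Bmp ligands had 4 of 59 members called higher and none lower, with a median of 0.049 at percentile 79.5. These were Bmp2 at 3.21 ± 0.35 over 3 probes, Gdf7 at 2.78 ± 1.83 over 5 probes, Gdf10 at 2.56 ± 0.43 over 4 probes and Wnt3 at 1.73 ± 1.17 over 6 probes. Ion channel and neurotransmitter receptor genes had 11 of 165 members called higher and 3 lower, with a median of 0.032 at percentile 78.8. Besides Htr1b and Kcnj3, the potassium channel gene Kcnk12 had 4.99 ± 0.84 over 2 probes and the glutamate receptor gene Grik1 2.77 ± 1.55 over 6 probes, while a second Grik1 region inside the gene had -0.55 ± 0.33 over 4 probes without a call. With uncentred ratios the median of this list was -0.037 and that of all genes -0.038. Its percentile ranged from 27.2 after normexp correction to 98.8 with means over probes.

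Imprinted genes, which are expressed from 1 parental copy, had 4 of 32 members called higher and none lower. Grb10, a growth-restraining adaptor gene, had a log2 ratio of 3.83 ± 0.31 over 3 probes, a 14.2-fold difference, in its promoter region on chromosome 11 from position 11937756. A second Grb10 region, inside the gene from position 11927926, had 0.52 ± 0.39 over 3 probes and was not called. Dio3, which encodes an enzyme that inactivates thyroid hormone, had 2.63 ± 2.52 over 4 probes, of which 2 were well above background at 3 months. Igf2r had 1.74 ± 1.11 over 2 probes and Zrsr1 1.48 ± 0.44 over 3 probes, of which 2 were well above background at 3 months. Dio3 and Zrsr1 lost their call after normexp correction, at 0.61 and 0.49. The list median of 0.018 lay at percentile 49.3, so the list did not stand apart by its median. Its share of genes called higher, 12.5%, was above the 2.29% of all genes, without matching on brightness. A list of genes with methylation reported in colorectal cancer or aged colon had 5 of 49 members called higher and none lower, with a median of 0.083 at percentile 88.7. Its leading members were Crabp1, a retinoic acid binding protein gene, at 3.52 ± 1.57 over 5 probes, and Gata4, a gut and heart factor, at 2.04 ± 1.33 over 6 probes. Neurog1 followed at 1.59 ± 2.40 over 5 probes and Cdh13 at 1.56 ± 0.075 over 2 probes. Crabp1 was no longer called after normexp correction, at a median of 4.07 with the lowest probe at -0.013, and Cdh13 with dim probes kept, at 0.013. The percentile of the list ranged from 28.2 after normexp correction to 99.5 for probes well above background in both samples. This list shares 6 genes with the developmental transcription factors, 3 of them called higher.

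Marker genes of the cell types that intestine holds had list medians inside the central 95% of matched random lists. Under the alternatives the percentile ranged from 54.5 to 99.2 for intestinal epithelium, the latter with block medians removed, and from 61.3 to 97.8 for enteric neurons and glia, the latter with dim probes kept. Immune cell genes had a median of -0.012 over 56 genes at percentile 22.6, with 3 called higher, namely Bcl11b at 2.01 ± 0.16 over 4 probes, Ltb at 1.63 ± 0.15 over 2 probes and Tbx21 at 1.62 ± 0.047 over 4 probes. Smooth muscle and stromal genes had a median of 0.034 over 28 genes at percentile 57.4 with no member called. Genes of enteric neurons and glia had 0.057 over 18 genes at percentile 70.1 with no member called. Intestinal epithelium genes had 0.093 over 44 genes at percentile 94.5 and 3 members called higher. These were Apoa4, an apolipoprotein gene of enterocytes, at 3.22 ± 0.76 over 3 probes, Gata4, and Spdef, a goblet cell factor gene, at 1.04 ± 0.51 over 4 probes. Gata4 belongs to 3 of the lists.

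Genes of DNA methylation and chromatin regulators had a median of 0.15 over 35 genes, at percentile 99.1, with 1 member called, Ezh2, at -1.06 ± 0.36 over 4 probes. The direction of that call was thus opposite to the list median, and the call did not hold under every setting. Over all alternatives the percentile of this list ranged from 63.2 to 99.1. Olfactory and vomeronasal receptor genes had a median of -0.045 over 412 genes at percentile 0.14, with 4 called higher and 5 lower. Restricted to probes well above background in both samples, that median was 0.0098 at percentile 35.6, so its sign turned when dim probes were left out. Olfr368, at -1.31 ± 0.39 over 4 probes, was the member with the most usable probes among those called and named. Olfr1370 at 1.58 ± 1.26, Olfr663 at 1.43 ± 1.21 and Olfr401 at 1.38 ± 1.95 rested on 2 probes each, and in each case 1 of these was well above background at 3 months. With dim probes kept Olfr1370 and Olfr401 turned sign, at -0.014 and -0.041.

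**Figure D2:**
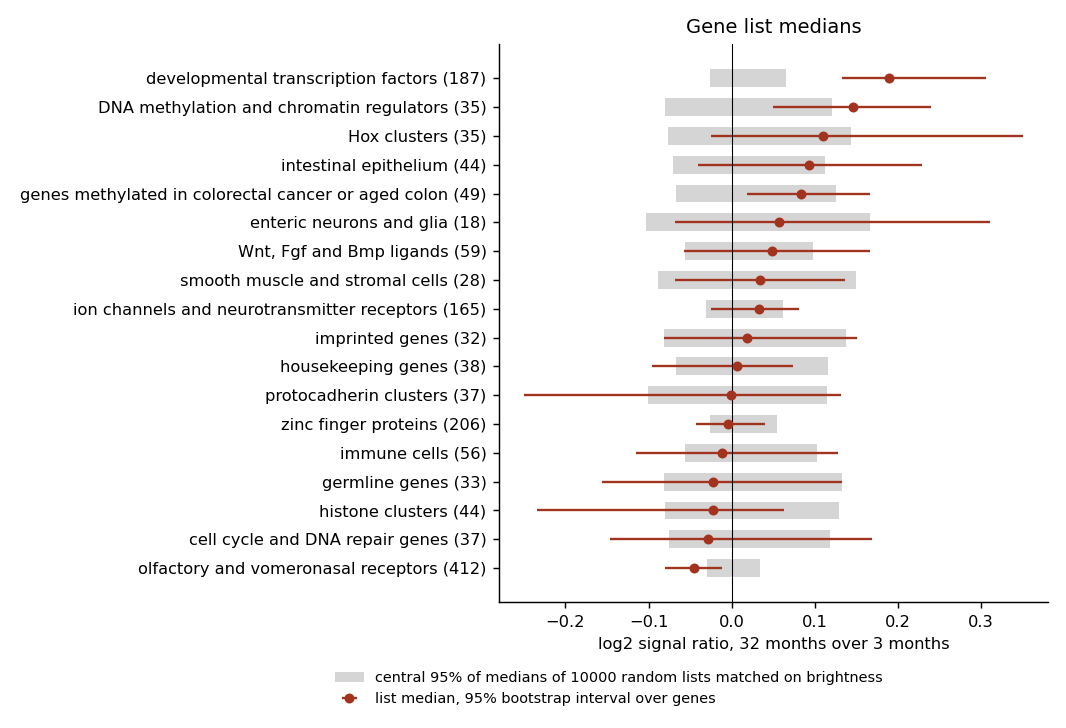
Median log2 signal ratio (32 over 3 months) of each of the 18 gene lists (points), with the number of measured genes in brackets. Red lines are 95% bootstrap intervals over genes and grey bars hold the central 95% of medians of 10000 random lists matched on brightness. Developmental transcription factors, at 0.19, lie outside their grey bar by the widest margin.

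The remaining lists lay within the central range of matched lists. Histone cluster genes had a median of -0.023 over 44 genes at percentile 22.8. Under the alternatives they lay between percentiles 0 and 37.9, and below the central range with uncentred ratios, after loess correction and for probes well above background in both samples. The 3 called regions of this list were each shared by 2 divergently transcribed genes, and they gave 4 genes called lower and 2 called higher. The shared promoter of H2ac22 and H2bc22 had -1.53 ± 0.55 over 2 probes and that of H2ac12 and H2bc12 -1.51 ± 0.19 over 2 probes, while that of H2ac6 and H2bc4 had 1.14 ± 0.061 over 2 probes. Zinc finger protein genes had a median of -0.0039 over 206 genes at percentile 21.7, with a range from 0.050 after normexp correction to 69.9. Among them Zfp536 had 3.65 ± 1.67 over 7 probes and Zfp710 -1.18 ± 1.20 over 4 probes, and the promoter shared by Gemin7 and Zfp296 had -1.38 ± 1.43 over 4 probes. A second region of Zfp536 had -0.23 ± 0.21 over 4 probes and a second region of Gemin7/Zfp296 -0.74 ± 0.54 over 3 probes, neither of them called. Germline genes had a median of -0.023 over 33 genes at percentile 23.1, and housekeeping genes 0.0062 over 38 genes at percentile 40.1, with no call in either. Protocadherin cluster genes had -0.0010 over 37 genes at percentile 48.2 with no call. Cell cycle and DNA repair genes had -0.028 over 37 genes at percentile 18.3, with Rb1 called higher at 1.05 ± 0.36 over 4 probes. Of the named list members, Hoxa6 and Ezh2 were not called under 4 of the 8 alternatives run for named genes, and Hoxc5, Neurog1, Spdef and Rb1 under 3. Gata4, Grik1 and Zfp710 were not called under 2. Olfr401, Olfr663 and Olfr1370 had too few probes well above background in both samples to be measured under that alternative. Of their remaining 7 alternatives Olfr401 was not called under 3 and the other two under 2. Besides Dio3, Zrsr1, Crabp1 and Cdh13, the 3 histone promoters, Olfr368 and the promoter of Gemin7 and Zfp296 were not called under 1. For some of them the median stayed past the threshold and the call ended because a probe no longer lay on the same side of 0. This held for Gata4 at 1.90 with uncentred ratios and 1.89 after loess correction, Grik1 at 2.63 and 2.70, Neurog1 at 1.45 and 1.56, Olfr401 at 1.31 with uncentred ratios and Hoxc5 at 2.01 after normexp correction. Values just short of the threshold remained for Spdef, at 0.90, 0.87 and 0.99 with uncentred ratios, after loess and after normexp correction, and for Rb1, at 0.92, 0.88 and 0.92 with uncentred ratios, after loess and with block medians removed. The promoter of H2ac6/H2bc4 had 1.00 with uncentred ratios, below the threshold before rounding, and Hoxc5 had 0.98 uncentred and 0.79 with dim probes kept. After normexp correction the medians shrank to -0.20 for Hoxa6, -0.27 for Ezh2, 0.66 for Neurog1, 0.36 for Olfr401, 0.10 for Olfr663, 0.85 for Olfr1370, -0.79 for Olfr368, -0.44 for Zfp710, -0.85 for Gemin7/Zfp296 and -0.59 for both H2ac22/H2bc22 and H2ac12/H2bc12. Hoxa6 had -0.92 after loess correction, -0.98 with block medians removed and -0.12 with dim probes kept, and Ezh2 had -0.93 after loess correction and -0.78 both with dim probes kept and for probes well above background in both samples. With dim probes kept Olfr663 had 0.057 and Zfp710 -0.58.

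Several genes were followed whatever their values. The DNA methyltransferase genes were not called. Dnmt1 had 0.12 ± 0.31 over 3 probes, Dnmt3b 0.053 ± 0.15 over 3 probes, and the promoter region of Dnmt3a 1.22 ± 1.60 over 4 probes, with the lowest at -0.80. The region of Dnmt3a inside the gene had 0.32 ± 0.79 over 2 probes. The tumour suppressor gene Cdkn2a had 1.75 ± 1.05 over 3 probes, but its lowest probe lay at -0.021, so the region missed the demand for agreement among probes. It was called higher after loess correction, at 1.90, and after normexp correction, at 1.62. The promoter region of the growth factor gene Igf2 had -0.92 ± 0.47 over 3 probes and its region inside the gene -0.11 ± 0.10 over 4 probes. The intestinal homeobox gene Cdx2 had -0.023 ± 1.03 over 3 probes. Esr1 and H19 had no region under those names and were not analysed here.

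The regions lower at 32 months were led by X-linked genes. Ap1s2, a gene of vesicle transport, had a log2 ratio of -5.14 ± 1.28 over 3 probes on chromosome X from position 159252611, with median signals of 146000 at 3 months and 3750 at 32 months. Bcap31, which encodes a protein of the endoplasmic reticulum, had -5.04 ± 0.68 over 3 probes, the ephrin gene Efnb1 -4.98 ± 0.51 over 6 probes and Mid1ip1 -4.85 ± 2.56 over 5 probes. Pdzd4 had -3.90 ± 0.70 over 5 probes. Mbnl3 at -4.64 ± 2.96, Smarca1 at -3.52 ± 2.89 and Uba1 at -2.57 ± 2.70 rested on 4 probes each, of which 3 were well above background at 32 months. Klf8 had -2.55 ± 2.79 over 5 probes. Of the 12 largest named differences in this direction, the 3 outside the X chromosome were Cbwd1 at -2.80 ± 0.79, Arhgef3 at -2.46 ± 1.43 and the GABA receptor gene Gabrg3 at -2.33 ± 1.22, each over 3 probes. Further autosomal regions, looked up after these values were seen, were Tas2r119 at -1.94 ± 0.76 over 4 probes, Adgrb2 at -1.92 ± 0.92 over 5 probes, the promoter region Ptpru/Mecr at -1.89 ± 0.97 over 4 probes, Cep97 at -1.84 ± 1.47 over 4 probes, and Espn at -1.75 ± 0.68 over 9 probes. Second measured regions of Uba1, Klf8, Arhgef3, Espn and Ptpru/Mecr were not called, at -0.24, 0.033, 0.082, 0.14 and -0.38. Several of the calls depended on the processing. After normexp correction Mid1ip1, Uba1, Gabrg3, Espn, Klf8, Tas2r119, Ptpru/Mecr and Cep97 were no longer called, at -3.85, -2.08, -1.67, -1.26, -0.60, -0.61, -0.30 and -0.90. With dim probes kept Ap1s2, Mbnl3, Cbwd1, Uba1, Arhgef3, Gabrg3 and Cep97 were not, at -4.84, -2.29, -0.89, -0.57, -0.093, -0.15 and -0.62. Espn lost its call after loess correction, at -1.85, and Arhgef3 with block medians removed, at -2.44. Where the median was still at or below -1 in these cases, the call ended because a probe lay above 0.

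Of 508 measured X regions 20 (3.94%) were called lower and 3 higher, whereas 33 of 7310 autosomal regions of the same array (0.451%) were called lower and 202 higher. The median X region lay 0.16 below the median autosomal region, with a 95% bootstrap interval of the difference from -0.19 to -0.12. The difference was -0.048 when dim probes were kept. The gap widened with brightness. In regions with a mean log2 signal of at least 12, the median was -1.41 over 34 X regions and 0.33 over 311 autosomal regions, and 26.5% against 2.57% were called lower. Y-linked probes were dim in both samples. The 8 usable probes of Rbmy1a1, a multi-copy gene of spermatogenesis, had a median log2 ratio of 1.28 and all lay above 0, while the other 25 usable Y probes had a median of 0.11 and 14 of them lay above 0. Among these other Y probes 20 were well above background at 3 months and 20 at 32 months. Of 10 Rbmy1a1 probes 6 were well above background at 3 months and 8 at 32 months.

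**Figure D3:**
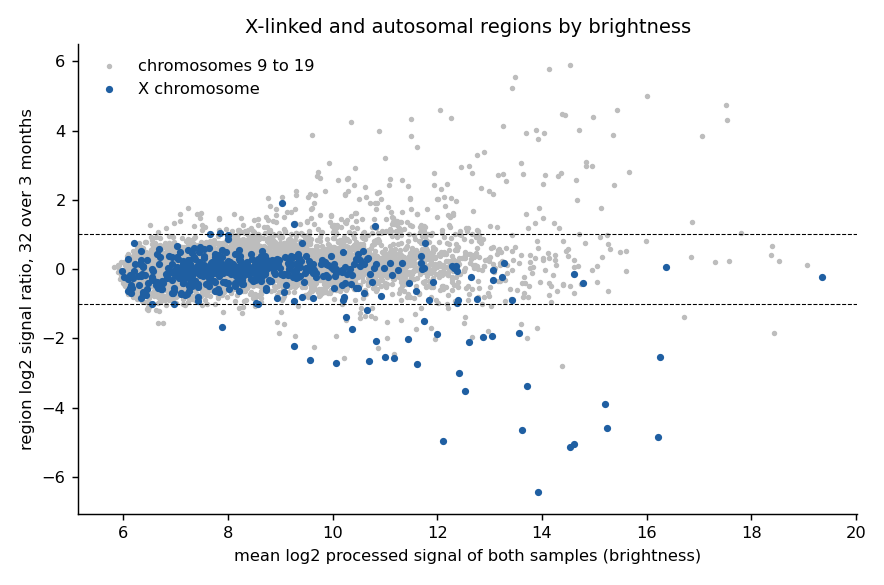
Region log2 signal ratio (32 over 3 months, vertical axis) against mean log2 signal of both samples (horizontal axis) for the second array. Blue points are the 508 X regions and grey points the 7310 autosomal regions, with dashed lines at 1 and -1. Bright X regions spread below 0 while bright autosomal regions spread mostly above it.

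Calls were unevenly spread over chromosomes and sequence classes. Higher calls made up 1.36% of measured regions on the first array and 2.76% of autosomal regions on the second. Among autosomes chromosome 18 had the highest share, with 15 of 376 regions called higher, and chromosome 3 the lowest, with 7 of 720. Of 9 measured Y regions 2 were called higher. Log ratios were also more widely spread on the second array, with an SD over usable probes of 0.83 against 0.63. Apart from the 84 regions of chromosomes 9 and 17 on the first array, the arrays hold different chromosomes, so array and chromosome were largely confounded. Among autosomal regions, those in the upper tercile of CpG content of the probes were called higher in 2.95% of 4945 cases (Wilson 95% interval 2.52% to 3.46%) and those in the lower tercile in 1.13% of 4947 cases (0.873% to 1.47%). Lower calls made up 0.506% and 0.465% of these classes. Regions annotated only as promoter were called higher in 3.69% of 2007 cases (2.95% to 4.60%), against 1.66% of 9220 regions that combine promoter and gene body probes (1.42% to 1.94%) and 2.13% of 2114 regions inside genes (1.60% to 2.84%). Regions between divergently transcribed genes were called lower in 1.20% of 1004 cases (0.685% to 2.08%). These intervals cover the counting of regions on these arrays only. The classes were not matched on brightness, number of probes or array. Brightness matters for such shares. Among autosomal regions of the second array 0.433% were called higher at a mean log2 signal below 8 and 21.5% at 12 or more. Whether the class differences hold at equal brightness was not tested.

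**Figure D4:**
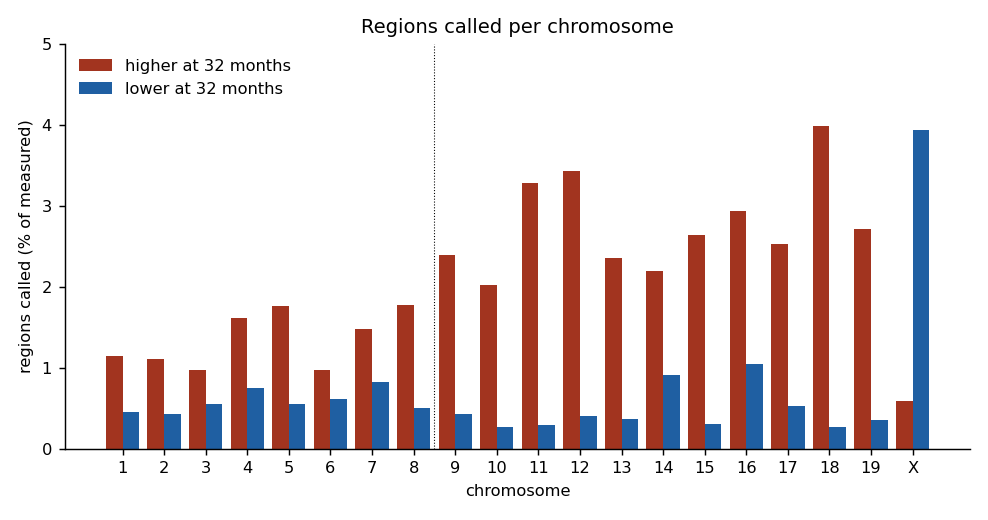
Percent of measured regions called higher (red) and lower (blue) at 32 months on each autosome and the X chromosome, with a dotted line between the chromosomes of the first and the second array. Among autosomes higher calls reach 3.99% on chromosome 18, and lower calls are most frequent on the X chromosome at 3.94%.

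Probes of a region repeated each other's sign in most regions with a large difference. In 8102 regions with at least 4 usable probes, the medians of odd and even probes correlated across regions with Pearson r = 0.57 and Spearman rho = 0.30, regions not being independent replicates. The correlation was 0.81 in the 437 regions with a mean log2 signal of at least 12 and 0.42 in the others. Where the odd probes had a ratio of at least 1, the even probes were above 0 in 293 of 330 regions. Where the odd probes had a ratio of at most -1, the even probes were below 0 in 95 of 118 regions.

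Absolute brightness did not separate promoters of germline genes, which are methylated in somatic tissue, from promoters of housekeeping genes, which are not. At 3 months the mean brightness percentile was 51.1 ± 26.2 (SD, 31 genes) for germline genes and 50.4 ± 25.8 (SD, 34 genes) for housekeeping genes, with p = 0.91 in a two-sided permutation test over genes. At 32 months the values were 52.5 ± 26.1 and 50.3 ± 25.3, with p = 0.73 in the same permutation test. The Benjamini-Hochberg adjusted value was 0.91 for both, and genes are not replicates of the animals. The brightness of these lists thus left open whether signal follows methylation.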

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

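The count of regions called higher at 32 months (309) stayed within 1.5 times under 14 of 19 alternatives, and that of regions called lower (97) under 9 of 19. A 1.5-fold threshold gave 679 higher and 344 lower, a 4-fold threshold 101 and 22, and the first array alone 102 and 44, by construction, as did the second array alone with 53 lower. Lower calls numbered 20 after normexp, 56 with no brightness filter, 208 with a minimum of 1 probe, 60 with 3 and 157 with no demand on probe agreement. Of 3 alternatives chosen after seeing the data, the rule of 2 neighbouring probes gave 626 and 257 calls, scaling the second array to the first gave 199 higher calls, and autosomes alone gave 304 and 77.

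Of 162 list medians under alternatives 149 stayed within a bootstrap interval redrawn for this comparison. By the intervals of the main results, chromatin regulators uncentred, at 0.032 against 0.049 to 0.24, would also lie outside. The same holds for ion channels with means over probes, at 0.085 against -0.024 to 0.081. Developmental transcription factors had 0.13 uncentred, 0.31 after normexp and 0.12 unfiltered. Ion channels had -0.037 uncentred and 0.12 after normexp, and zinc finger proteins -0.048 uncentred, 0.054 after loess and 0.086 after normexp. Olfactory receptors had -0.10 uncentred and 0.0098, with the sign turned, for probes bright in both channels. After normexp imprinted genes had 0.20, housekeeping genes 0.16 and histone clusters 0.064, with the median of all genes at 0.11 in place of 0.014, and uncentred it was -0.038. The X chromosome shift was -0.12 after normexp, -0.12 for probes bright in both channels and -0.048 unfiltered. The excess of higher calls in CpG-rich over CpG-poor regions was 2.95 percentage points at 1.5-fold against 1.82. The odd and even probe correlation was 0.68 with at least 6 probes and 0.61 for probes bright in both channels. Among 72 named regions, 509 of 573 alternative values stayed called or uncalled as before, 60 lost the call, 2 gained it, Cdkn2a at 1.90 after loess and 1.62 after normexp, and 2 turned sign, Olfr1370 at -0.014 and Olfr401 at -0.041, both unfiltered. Except for the settings that by construction test fewer or more regions, the cause was not tested. The value-table alternative repeated the main values. Signal over background limits dim regions. No paired analysis was possible because each group holds 1 sample, and for the same reason no sample could be left out.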

Other observations

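The tests on X-linked regions were chosen only after that result was seen, as were the values in the next paragraph. The other tests were set before their results were seen.

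Several imprinted regions were among the brightest on the arrays at both ages. Of 42 regions of imprinted genes, 6 lay above the 95th brightness percentile of their array in both samples. The Cdkn1c region lay at percentiles 99.9 and 100 at 3 and 32 months, a Gnas region at 99.7 and 99.7, a Mest region at 98.2 and 97.5 and the Nnat region at 97.1 and 96.5. The Grb10 region named above lay at 99.7 and 100. Other regions of the same genes were less bright. At 3 and 32 months they lay at 29 and 46 and at 58 and 74 for Gnas, at 32 and 35 for Mest and at 19 and 34 for Grb10. The mean percentile over the 42 regions was 60.7 at 3 months and 63.2 at 32 months. Among 160 families of at least 10 autosomal genes with a common symbol root, Tbx genes had the highest percentile among matched lists, 99.9, with a median log2 ratio of 0.34 over 12 genes. Of these 12 genes 1 was called higher. The Olfr family had the lowest, 0.15, with a median of -0.043 over 365 genes, and Cd genes followed at 0.30 with -0.075 over 76 genes. In a ranking of 160 families some lie near either end without any shift. T-box and olfactory receptor genes were also covered by lists above, so these values are not separate evidence.

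X-linked regions were called lower at 32 months in 3.94% of cases. In autosomal regions of the same array matched on brightness the share was 0.512%, which argues against a dye bias that depends on brightness. A difference in X copy number alone gives a log2 ratio near -1, yet 6 of the 20 called X regions had medians below -2 by more than the SD of their probes. A candidate explanation is that the 3-month sample came from females, whose inactive X carries methylated CpG islands, and the 32-month sample from males. It assumes that a higher signal means more methylation, which the brightness of germline and housekeeping genes left open. The median of 1.28 (SD 1.04 over 8 probes) for the Y-linked Rbmy1a1 goes with such a difference in sex, but those probes were dim and the other Y probes had a median of 0.11. Moreover, 6 of 10 Rbmy1a1 probes were well above background at 3 months, although a female sample holds no Y chromosome. Genes that escape X inactivation keep unmethylated CpG islands on the inactive X, so values near 0 are predicted for them. Of 4 such genes Kdm5c, Kdm6a and Eif2s3x had -0.17, -0.13 and -0.14, whereas Ddx3x, at -1.94 ± 1.32 over 6 probes without a call, went against the prediction. Since 485 of 508 X regions met neither rule and the median X region lay at -0.070, values near 0 do not set these genes apart. They therefore decide nothing about the explanation. An effect of age on the X chromosome stays open and untested.

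Of 187 developmental transcription factor genes 32 were called higher at 32 months, and the median log2 ratio of the list was 0.19. With random lists matched on both brightness, in 10 bins, and CpG content of the probes the list stayed at percentile 100. Brightness and CpG content as binned thus did not account for its median, but differences within the brightest bin were not matched. Among autosomal regions of the second array, 6.96% were called higher at a mean log2 signal of 10 to 12. At 12 or more that share was 21.5%. On autosomes alone the list median was 0.20 over 183 genes, so sex chromosome regions did not account for it, though few list genes lay there. A larger share of immune cell DNA at 32 months may contribute. The median of -0.012 of the immune list decides nothing, since it fell short of the limits set beforehand in either direction. Of the 56 genes of that list 3 were called higher and 0 lower. Age is the difference that the design names, and it could not be separated from sex, dye or the individual animals, because there is 1 sample per age.

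More autosomal regions were called on the second array than on the first, 3.21% against 1.94%, a ratio of 1.66. In regions with a mean log2 signal of at least 12 the ratio was 1.70 (95% interval 1.26 to 2.29), so the excess was not limited to dim regions. That cut is on processed signal, which was scaled by larger dye factors on the second array. These were 17.95 for green and 5.831 for red, against 9.238 and 3.081 on the first. Regions past the cut were thus not matched in raw signal, and a difference in noise between the arrays stays open. The median absolute deviation of log ratios was 0.33 on the second array and 0.21 on the first. With the second array scaled to the first the ratio was 0.754 (0.587 to 0.969), so the excess turned into a deficit. Such scaling lowers the calls of that array whatever made its ratios wider, so this test leaves a wider scale open. Of 83 regions of chromosome 9 placed on the first array 1 was called higher, which is too few to compare the arrays on 1 chromosome. The autosomes are otherwise held by 1 array each, apart from 1 region of chromosome 17, so a wider scale of the second array and a difference between chromosomes cannot be told apart.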
